A study of Arabidopsis thaliana with 12 samples.

How the data were processed

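RNA from Arabidopsis thaliana seedlings was sequenced in 12 libraries of polyadenylated RNA, 4 each from wild type (WT), the picln-1 mutant and the prmt5-5 mutant. Per the labels, seedlings grew at 22 °C for 10 days under 12 h light and 12 h dark, with 9 days of that light regime given as the treatment. Nothing in the labels says that the 4 libraries of a genotype came from separate cultures, so the p-values may measure only the spread between these libraries. The series' design line speaks of cold treatment, whereas the labels of all 12 libraries give only the light regime, which was followed here.

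The material used was 4 tables of the authors' own comparisons: gene expression and bin usage for picln-1 against WT, and the same for prmt5-5 against WT. A bin is a stretch of a gene between annotated splice sites, so that an intron, an exon or an alternative part of an exon is counted apart. TopHat and the TAIR10 genome are named in the submitters' processing notes, and the program that counted and tested the reads is not given in the sources used here. Expression and bin usage changes are log2 fold changes computed by the authors as mutant over WT. The deposited headers give no base of the logarithm, and base 2 was taken because the smallest change listed in the gene tables, 0.58, then equals a 1.49-fold or 1.50-fold change. The p-value and the Benjamini-Hochberg adjusted p-value of each gene or bin are the authors' own, per the file headers. For each bin the authors deposited a fraction per genotype, pooled over its libraries: the share of junction reads that retain the intron or include the exon part. These fractions were multiplied by 100 and are given as percentages.

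The deposited description limits the gene tables to an adjusted p below 0.05 and the bin tables to an adjusted p below 0.15 with a change of the fraction above 0.05. Each listed gene also changed by at least 0.58 on the log2 scale, a limit that the description does not state. Only features past these limits are listed, so a gene described as not listed was either unchanged, changed by less, or not tested. The tables give no standard errors and no values per library, and sequencing depth is unknown. The planned count tests, the refits without each replicate and the fit with a replicate block need counts per library and could not be run, so the authors' calls were counted as deposited and no test per gene or bin was made. For the same reason an adjustment over a gene list alone could not be made for single genes.

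The number of features behind each table was recovered from the ratio of adjusted to raw p, which equals that number divided by the rank: 16473 genes and 112984 bins for picln-1, and 16747 genes and 118209 bins for prmt5-5. Gene names, classes and neighbours were taken from the RefSeq annotation of TAIR10.1, whose 38095 loci, 27550 of them protein-coding, served as background. Its chromosome sequences were compared with the TAIR10 positions in the tables through introns: 99.4% of the called intron bins of picln-1 and 99.5% of those of prmt5-5 had start and end equal to an annotated intron. Intron numbers and the position in coding sequence or untranslated region (UTR) come from that match. They refer to the first annotated transcript that holds the intron, so other transcripts of the gene may number or place it differently.

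The direction of called intron bins was tested with exact two-sided binomial tests with 95% Clopper-Pearson intervals. Event mixes, gene lists and the joint occurrence of expression and splicing changes were tested with two-sided Fisher's exact tests, and the overlap between mutants with one-sided Fisher's exact tests for excess. The 9 gene lists, holding 198 loci, were fixed before the data were examined, and p-values of lists were adjusted by Benjamini-Hochberg over the 9 lists within each table. Because both mutants were compared with the same WT libraries, 100 simulations of unchanged mutants against a shared control gave the overlap, correlation and share of equal signs that arise with no effect. The share of introns called in a mutant that would lie above WT in the other with no effect in either was computed from the called p, with equal spread assumed in the 3 genotypes. An approximate standard error of each log2 change, its size divided by the normal quantile of its p, served to compare changes between mutants. Splice sites were scored in bits with a position weight matrix over 9 bases at the 5' splice site (3 exon and 6 intron bases), built from the annotated introns. Called and uncalled introns of the same gene were compared by sign-flip permutation with 100000 draws, for which the smallest possible p is 1e-05. On simulated data the number of tests was recovered in 4 of 4 tables, the overlap test found 40 planted shared genes in 100 of 100 runs and called chance in 2 of 100, and the sign-flip test called chance in 6 of 100 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

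Genes were named by a rule fixed before the data were examined: per mutant the 10 largest rises and the 10 largest falls, up to 15 called members of the lists by smallest adjusted p, and both mutated genes. Bins were named as the 5 largest gains, the 5 largest losses, the 5 smallest adjusted p and up to 15 bins in list genes, and not every bin that this rule selects is printed in the text. Further list members and bins that differ in direction between the mutants are named outside that rule and were chosen after their values were seen. Alternatives tried were an adjusted p below 0.01, a log2 change of at least 1, 1 bin per gene, other backgrounds and, chosen after seeing the data, the recovered number of genes tested as background, the direction read from the retained fraction, and the removal of features with values identical to another gene's.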

Results

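Transcripts of Arabidopsis seedlings were compared between wild type (WT) and mutants of 2 factors tied to the assembly of spliceosomal small nuclear ribonucleoproteins (snRNPs): pICln, an assembly chaperone, and PRMT5, an arginine methyltransferase. There were 4 libraries of each of the 3 genotypes, WT, picln-1 and prmt5-5. The data are the authors' lists of genes with changed expression and of gene bins with changed usage in each mutant, with no standard errors, no values per library and unknown depth. Both mutants were compared with the same WT libraries.

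The mutated genes were read before any other. In picln-1, the pICln transcript (AT5G62290, TAIR10 chromosome 5, 25019175 to 25021131) was 11.2-fold lower than in WT (log2 change -3.48, adjusted p = 1.65e-94 in the authors' deposited table). pICln was not listed in prmt5-5. PRMT5 (AT4G31120) was not listed for a change of expression in either mutant, but its intron 20 of 22, in the coding sequence (chromosome 4, 15132630 to 15132724), was retained in 81.0% of junction reads in prmt5-5 against 0.870% in picln-1 and 0% in WT in the authors' deposited table.

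The comparison of expression between picln-1 and WT asks which transcripts differ between the mutant line and WT. Each gene is represented by a single mutant genotype, so other differences between that line and WT cannot be told apart from the mutation. The floral repressor FLC was among the deepest falls in picln-1: it was 13.3-fold lower (log2 change -3.74, adjusted p = 7.29e-50 in the authors' deposited table; AT5G10140, chromosome 5, 3173382 to 3179448). PCC1 (AT3G22231), a gene controlled by pathogens and the circadian clock, fell by 4.09 on the log2 scale, and its neighbour AT3G22235 fell by 3.35, both from the authors' deposited table. Further deep falls in the authors' deposited table were AT5G27250 (log2 change -3.23) and AT2G25510 (-2.98). MRD1 (AT1G53480) and HEI10 (AT1G53490), a meiotic crossover factor, fell by 4.54 and 3.73 in the authors' deposited table. These 2 genes overlap on opposite strands on chromosome 1 (19963047 to 19964712 and 19963267 to 19966952), and no strand setting of the counting is given, so their reads cannot be told apart. On the rising side, QQS (AT3G30720), an orphan gene linked to starch content, was 27.5-fold higher (log2 change 4.78, adjusted p = 5.09e-283 in the authors' deposited table). The largest rises in the authors' deposited table were AT3G28899 (log2 change 6.32) and AT5G35935 (5.54), and AT1G47405 (3.66), AT1G67105 (2.80), AT1G15405 (2.26), the retroelement SADHU3-2 (1.85), the glucosinolate hydrolysis gene ESM1 (1.68) and the histone H3-like gene HTR11 (1.65) were also among the 10 largest.

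In all, the authors' deposited table for picln-1 lists 279 genes, 115 higher and 164 lower than in WT, out of 16473 genes tested. The median listed rise in the authors' deposited table was 1.67-fold and the median listed fall 1.74-fold. By adjusted p alone at least 2145 genes passed, so the list holds 13.0% of them, those with changes of at least 0.58 on the log2 scale.

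Among the fixed gene lists, 3 of 35 snRNP and spliceosome genes were listed in picln-1. They are pICln itself, the U1 snRNP protein gene U1-70K (AT3G50670), which fell by 0.83 on the log2 scale, and the Sm-core gene SMD1A (AT3G07590), which rose by 0.71, values from the authors' deposited table. All 3 listed members of the 23 biotic defence genes fell in the authors' deposited table: the regulator WRKY70 (log2 change -0.88) and the vegetative storage protein genes VSP2 (-0.89) and VSP1 (-0.94), a pair of close relatives between which reads could be split. The shade and light regulator HFR1 (-1.11), the clock output gene CDF1 (-0.87) and the dehydrin RAB18 (-1.05) also fell in the authors' deposited table. No member of the flavonoid, SR and hnRNP-like or seed storage lists was listed in picln-1. Against all annotated genes, the defence list (adjusted p = 0.00556, Fisher's exact test) and the snRNP list (adjusted p = 0.00962) held more listed genes than chance gives. The snRNP count includes the mutated gene pICln, so that excess is not independent of the choice of mutant. With the 16473 genes tested as background, the exact tests gave adjusted p = 0.0596 and 0.0950, so neither call held.

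**Figure D1:**
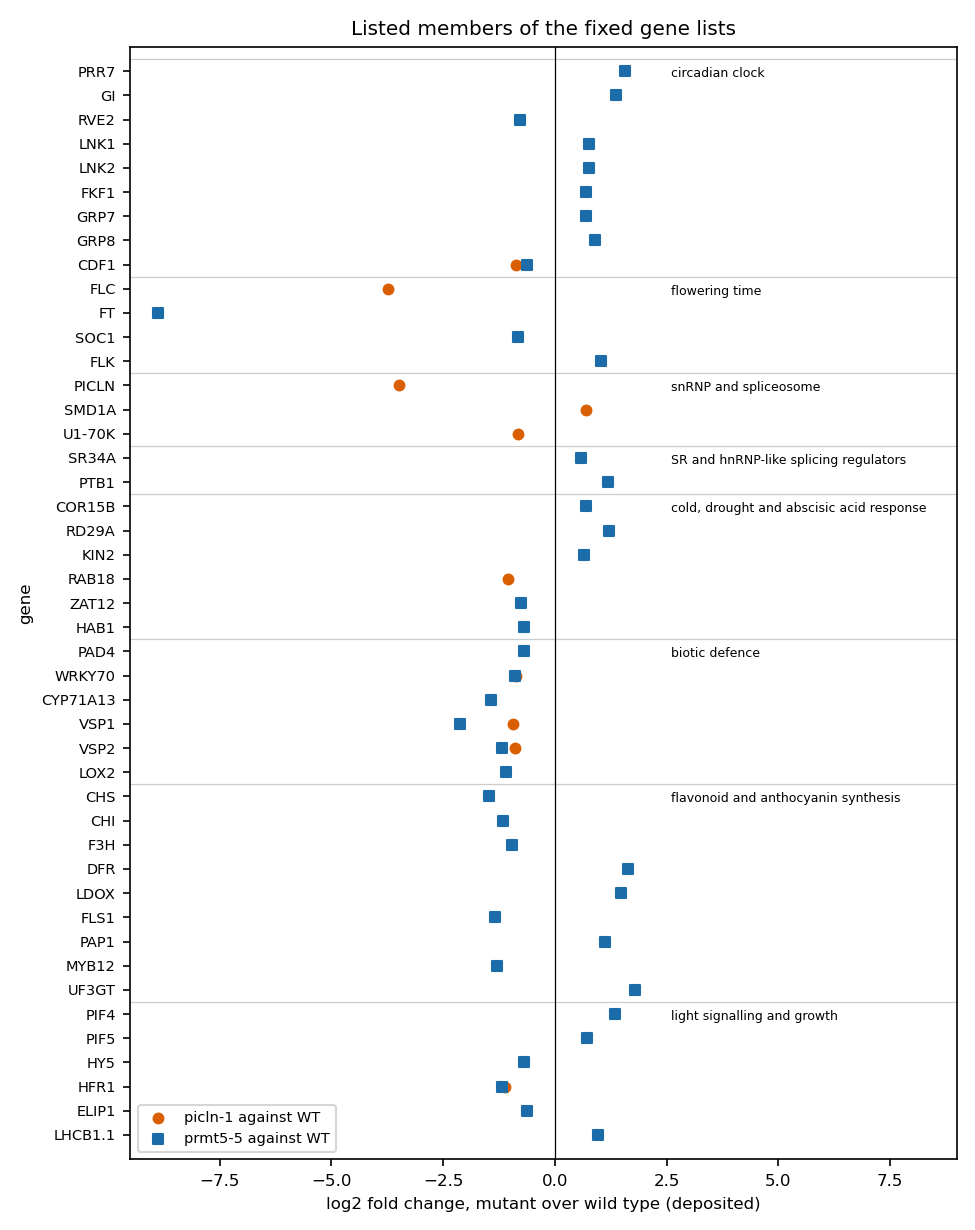
Log2 fold change over WT (horizontal axis) of each gene of the fixed lists (rows, grouped by list) that the authors' deposited tables list; circles are picln-1, squares prmt5-5, each point 1 comparison of 4 with 4 libraries, with no error given. FT lies lowest at -8.88 in prmt5-5, and the biotic defence genes lie below 0 in both mutants; GRP7 and GRP8, members of 2 lists, are drawn once.

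The comparison between prmt5-5 and WT asks the same of the prmt5-5 line, with the same limit. FT (AT1G65480, chromosome 1, 24331373 to 24333999), which encodes the mobile flowering signal, fell furthest (log2 change -8.88, adjusted p = 3.66e-42 in the authors' deposited table). How near 0 its reads lay in prmt5-5 is unknown, so that size is a fitted value. The flowering integrator SOC1 fell by 0.82, and FLK, which encodes an RNA-binding protein that promotes flowering, rose by 1.04 in the authors' deposited table. FLC was not listed in prmt5-5, nor FT in picln-1. PCC1 fell by 4.25 on the log2 scale and AT3G22235 fell by 3.29 in the authors' deposited table, as they had in picln-1. Other deep falls in the authors' deposited table were AT5G50310 (log2 change -3.36), AT2G16005 (-3.11), AT2G05510 (-2.83), M17 (-2.72) and AT1G03020 (-2.58). The largest rises in the authors' deposited table were AT5G28335 (log2 change 4.94), AT3G55240 (4.81), MPC (4.21), AT1G77960 (3.76) and PYD4 (3.53), a gene of pyrimidine breakdown. TGA9, a transcription factor gene of anther development, rose by 2.64, AT1G12730 by 2.51, the light-harvesting gene LHCB2.2 by 2.40 and AT2G25760 by 2.26 in the authors' deposited table.

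The authors' deposited table for prmt5-5 lists 1531 genes, 836 higher and 695 lower, out of 16747 tested. At least 6840 genes passed by adjusted p alone, of which the list holds 22.4%.

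Flavonoid and anthocyanin genes stood out in prmt5-5, with 9 of 13 listed, in opposite directions. The early steps and their regulator fell in the authors' deposited table: chalcone synthase CHS (log2 change -1.48), chalcone isomerase CHI (-1.15), F3H (-0.96), flavonol synthase FLS1 (-1.34) and the flavonol regulator MYB12 (-1.30). The late anthocyanin genes rose in the authors' deposited table: DFR (1.64), LDOX (1.48), the glycosyltransferase UF3GT (1.79) and the regulator PAP1 (1.13), with adjusted p between 0.00180 and 0.00703. Of 24 circadian clock genes 9 were listed, 7 higher and 2 lower. In the authors' deposited table the core and output genes PRR7 (1.56), GI (1.37) and FKF1 (0.70), the coactivators LNK1 and LNK2 (0.76 each) and the RNA-binding protein genes GRP8 (0.89) and GRP7 (0.71) rose, while RVE2 (-0.77) and CDF1 (-0.63) fell. Light signalling genes went both ways, with 6 of 14 listed. PIF4 rose by 1.35, PIF5 by 0.71 and LHCB1.1 by 0.97, and HFR1 (log2 change -1.17), HY5 (-0.69) and ELIP1 (-0.61) fell in the authors' deposited table. All 6 listed members of the 23 defence genes fell, from PAD4 (log2 change -0.68) to VSP1 (-2.13) in the authors' deposited table, with the camalexin gene CYP71A13 at -1.42 and the jasmonate gene LOX2 at -1.10. Among 30 cold, drought and abscisic acid genes, RD29A rose by 1.2, COR15B by 0.69 and KIN2 by 0.65, and ZAT12 and the phosphatase gene HAB1 fell by 0.75 and 0.68 in the authors' deposited table. The polypyrimidine tract-binding protein gene PTB1 rose by 1.2 and SR34A by 0.59 in the authors' deposited table, and no snRNP gene was listed.

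Against all annotated genes, the flavonoid (adjusted p = 1.49e-09, Fisher's exact test), clock (9.09e-07), light signalling (2.85e-05) and defence lists (0.000525) were enriched. With the genes tested as background their adjusted p were 2.00e-06, 0.000720, 0.00273 and 0.0337. The cold list (adjusted p = 0.0116) and the SR and hnRNP-like list (0.0251) passed only against all annotated genes, with adjusted p = 0.285 and 0.361 in the exact test against the genes tested. The flowering (0.119), snRNP (0.453) and seed storage lists (1, with 0 of 9 members listed) did not pass.

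The bin tables ask which splicing events changed. In picln-1, the event with the smallest adjusted p was a gain of splicing: intron 6 of 8 of U1-70K (chromosome 3, 18827440 to 18828348) was retained in 29.0% of junction reads in WT and in 5.50% in picln-1 (log2 usage change -2.37, adjusted p = 2.17e-80), against 33.2% in prmt5-5, in the authors' deposited table. Introns of other splicing regulators also fell in picln-1 in the authors' deposited table: RS40 intron 3 from 26.9% to 13.6%, PTB1 intron 9 from 11.5% to 0.958% and GEMIN2 intron 1 from 35.1% to 21.2%. An SCL33 intron, in the 5' UTR of the matched transcript, fell from 51.0% to 35.8% in the authors' deposited table. Called bins of clock genes went both ways, with 5 higher and 2 lower in usage. TOC1 intron 4 of 5 (chromosome 5, 24676740 to 24676823) went from 8.55% to 29.8%, PRR3 intron 1 in the 5' UTR from 23.5% to 43.4% and BOA intron 1 in the 3' UTR from 2.39% to 9.92%, while ELF3 intron 2 fell from 40.7% to 28.0% and GRP8 intron 1 from 15.9% to 10.8%, all from the authors' deposited table. Among genes outside the lists, the auxin response factor gene ARF1 (5' UTR intron 1) went from 0% to 8.77%, ORG1 (intron 7) from 1.41% to 11.6% and the chromatin remodeller INO80 (intron 15) from 35.8% to 3.70% in the authors' deposited table.

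In all, the authors' deposited table lists 541 bins in 470 genes for picln-1, 484 with higher and 57 with lower usage, out of 112984 bins tested. Intron bins made up 523 of them, and 479 of these rose (91.6%, 95% Clopper-Pearson interval 88.9 to 93.8%, exact binomial p = 1.93e-93). In the rest were 6 skipped exons, 5 alternative 5' and 3 alternative 3' splice sites and 4 exon bins without an annotated event. Bins were listed only with a change of the fraction above 0.05, so an intron retained below that in WT could only rise. The WT median of the 479 was 4.53%, so the filter itself favours rises and no preference is read from the binomial p. Among called introns with a WT fraction above 0.1, 106 rose and 33 fell outside the snRNP and SR and hnRNP-like lists. Within those lists 0 rose and 7 fell. Bins were called in 6 of 25 SR and hnRNP-like genes and 6 of 24 clock genes (adjusted p = 2.23e-06 for each list, Fisher's exact test, and 0.000262 with the genes tested as background). Neither background was matched for the number of bins or reads per gene, so the list tests on bins may partly reflect those. Among bins with an adjusted p below 0.01 the clock list still passed (adjusted p = 0.000147, Fisher's exact test) and the SR and hnRNP-like list, with 2 of 25 genes, did not (0.0508). The snRNP list had 3 of 35 genes with a called bin, all lower in usage (adjusted p = 0.0273, Fisher's exact test, and 0.231 with the genes tested as background). The flowering list had 2 of 27 (adjusted p = 0.0979, exact test), and the defence, cold, flavonoid, light and seed lists had none.

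In prmt5-5, intron retention rose across many genes, in places to most junction reads. Intron 1 of the carotenoid cleavage gene CCD1 (chromosome 3, 23453156 to 23453236) went from 6.08% in WT to 92.8% (adjusted p = 1.70e-230 in the authors' deposited table). Retention rose in the authors' deposited table from 3.45% to 66.7% in intron 20 of the blue-light receptor gene PHOT2, from 7.84% to 71.0% in intron 2 of the drought gene RD22 and from 6.80% to 34.1% in intron 5 of the salt tolerance gene SOS3. Flowering regulators were among them in the authors' deposited table: intron 2 of MAF1 (chromosome 1, 28958502 to 28958601) went from 26.1% to 85.4%, and the 5' UTR intron of FLK (chromosome 3, 1254283 to 1254768) from 24.8% to 76.0%, with 53.1% in picln-1. Splicing factor genes gained retention in the authors' deposited table as well, with PTB1 intron 1 (5' UTR) going from 2.13% to 52.8%, SR45A intron 5 (3' UTR) from 39.4% to 78.1%, PTB3 intron 5 from 0.649% to 10.3% and the single 5' UTR intron of U2AF35A from 2.39% to 8.43%. Introns with 0% in WT reached 31.4% in the plastid division gene SULA, 14.6% in the starch gene SEX1 and 47.4% in AT1G12730 in the authors' deposited table. The few losses included intron 5 of the actin-related gene ARP2, from 11.1% to 0%, and alternative 5' splice sites of AT5G17530 (25.3% to 4.42%) and AT3G07760 (48.9% to 7.0%) in the authors' deposited table.

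**Figure D2:**
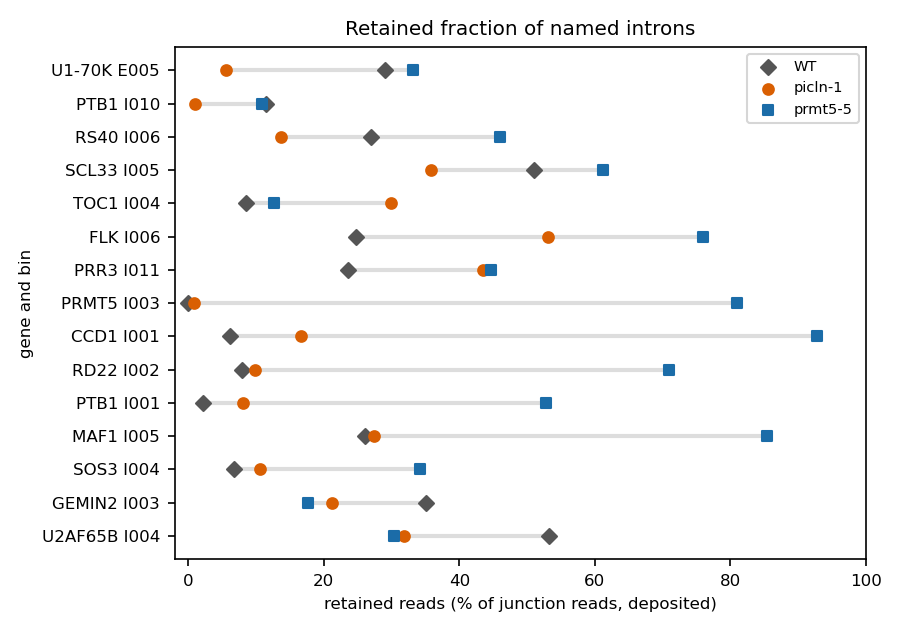
Retained reads as a percentage of junction reads (horizontal axis) for 15 named introns (rows: gene and bin as the authors' deposited tables name them) in WT (diamonds), picln-1 (circles) and prmt5-5 (squares), each a value pooled over libraries with no error given. U1-70K moves from 29.0% in WT to 5.50% in picln-1 and 33.2% in prmt5-5, and PRMT5 is retained at 81.0% in prmt5-5 against 0.870% in picln-1.

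The authors' deposited table for prmt5-5 lists 3406 bins in 2601 genes, 3335 higher and 71 lower, out of 118209 tested. Of 3362 intron bins, 3320 rose (98.8%, exact 95% interval 98.3 to 99.1%). The others were 20 alternative 5' and 7 alternative 3' splice sites, 12 skipped exons and 5 exon bins without an annotated event. Of the 20 alternative 5' splice sites, 15 were used less. As in picln-1, an intron retained in WT below the limit set on the change of the fraction could only rise. The WT median of the 3320 introns was 2.44%, so the filter itself favours rises and no preference is read from the 98.8%. Among called introns with a WT fraction above 0.1, 390 rose and 38 fell outside the snRNP and SR and hnRNP-like lists. Within those lists 4 rose and 2 fell. Bins were called in 12 of 25 SR and hnRNP-like genes (adjusted p = 2.02e-07, Fisher's exact test, and 0.00123 with the genes tested as background). The number of bins and reads per gene was again not matched, so more chances of a call may add to this excess. No other list passed the exact test: 6 of 35 snRNP genes (adjusted p = 0.133), 4 of 24 clock genes (0.232), 4 of 27 flowering genes (0.245), 2 of 30 cold genes and 1 of 14 light genes (1 for both), and 0 defence (0.722), flavonoid or seed genes.

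The same introns can be read in all 3 genotypes, because the bin tables give the retained fraction in each. For the 479 introns gained in picln-1, the median retained share was 4.53% in WT, 15.6% in picln-1 and 13.1% in prmt5-5, and prmt5-5 lay above WT in 454 of them, by the fractions in the authors' deposited table. For the 3320 introns gained in prmt5-5 the medians were 2.44% in WT, 4.59% in picln-1 and 15% in prmt5-5, with picln-1 above WT in 2569 of them, again from the authors' deposited table. Among the 237 introns gained in picln-1 and not called in prmt5-5, the medians in the authors' deposited table were 3.96% in WT, 14.4% in picln-1 and 7.27% in prmt5-5, with prmt5-5 above WT in 213. These introns were chosen for lying above the same WT libraries. With no effect in either mutant, 98.8% of those gained in picln-1 and 98.5% of those gained in prmt5-5 would lie above WT in the other mutant. These values treat every call as a low draw of WT, whereas at an adjusted p below 0.15 most calls should not be such draws. The observed shares, 94.8% and 77.4%, therefore cannot be judged against them. The share given by a true change in a single mutant was not computed, so these counts neither show nor exclude a shared change. Intron bins were 96.7% of calls in picln-1 and 98.7% in prmt5-5 (odds ratio 0.380, p = 0.00126, Fisher's exact test), a difference that no longer passed among changes of at least 1 on the log2 scale (odds ratio 0.479, p = 0.262). Calls in the mutants are not independent, since the WT libraries are shared.

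**Figure D3:**
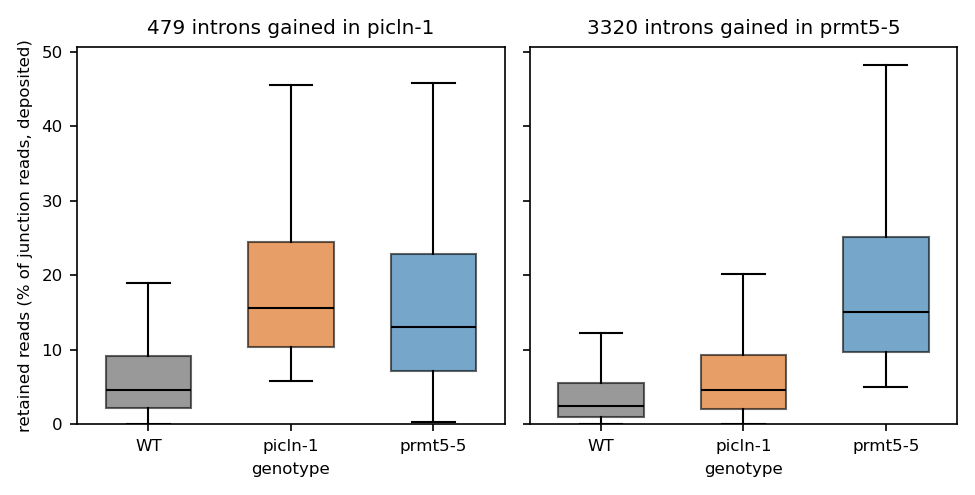
Retained reads as a percentage of junction reads (vertical axis) in WT, picln-1 and prmt5-5 for the introns gained in picln-1 (left, 479) and in prmt5-5 (right, 3320); boxes give quartiles and median over introns, whiskers reach the last value within 1.5 box lengths, and values beyond are not drawn. Medians on the left are 4.53%, 15.6% and 13.1%, and on the right 2.44%, 4.59% and 15%.

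How alike the mutants are was asked from the features listed in both. Shared falls included PCC1, AT3G22235, AT5G42530 (log2 change -3.33 in picln-1 and -3.29 in prmt5-5), AT5G03350 (-2.70 and -3.03), WRKY70 (-0.88 and -0.89) and HFR1 (-1.11 and -1.17), and shared rises AT4G04223 (2.36 and 2.26) and SADHU3-2 (1.85 and 1.88), values from the authors' deposited tables. In total 45 genes rose in both mutants by the authors' deposited tables, where independent lists give 2.52 against all annotated genes and 5.84 against the genes tested (p = 3.41e-44 and 1.23e-28, one-sided Fisher's exact test). Falls were shared by 72 genes, where independent lists give 2.99 and 6.92 (exact p = 1.44e-80 and 3.42e-55). Unchanged mutants against a shared control gave a mean of 8.56 and at most 18 shared rises, and a mean of 8.62 and at most 16 shared falls, in 100 simulations. The shared bins were 243 that rose and 14 that fell in both, where independent lists give 14.3 and 0.0358. The simulated shared control gave a mean of 20.1 and at most 30 shared bins that rose, and a mean of 19.7 and at most 31 that fell. It thus treated the directions alike, whereas the deposited lists hold 484 and 3335 rises but only 57 and 71 falls. Its lists per direction differ in length from these, so neither the 14 shared falls nor the 243 shared rises can be judged against it.

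Of the 122 shared genes 117 changed in the same direction (95.9%). With no effect this share was 66.2% over unselected genes but 100% among simulated genes called in both, so it does not show a shared change. Across these genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.858 and Spearman's rho of 0.780, against a simulated r of 0.499, and the covariance was 1.34 against a simulated 0.0161, both simulated values being over unselected genes. Of 260 shared bins 257 changed in the same direction, where simulated bins called in both gave 100%, so this share shows no shared change either. Their r was 0.794, rho 0.753 and covariance 0.818, against a simulated covariance of 0.0762 over unselected bins. The WT libraries could not be split between the comparisons, and choosing features called in both raises r and covariance by itself, so no excess over the simulated values is shown.

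**Figure D4:**
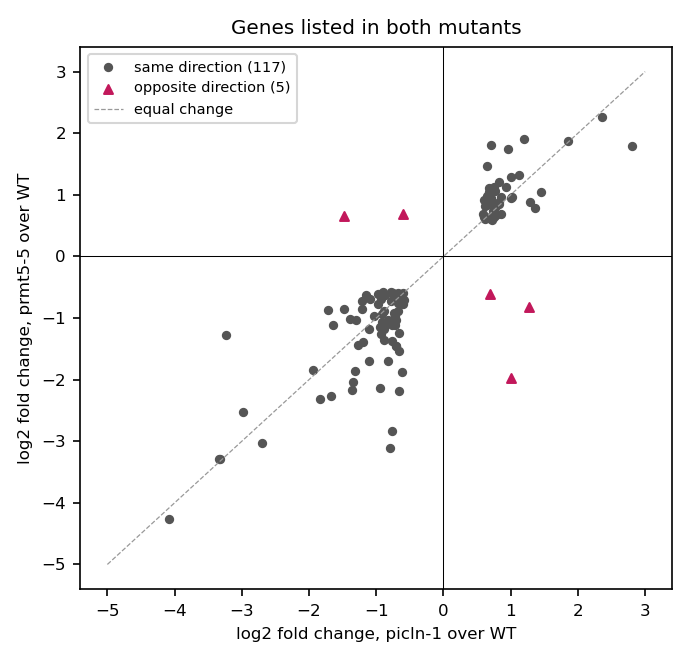
Log2 fold change over WT in prmt5-5 (vertical axis) against that in picln-1 (horizontal axis) for the 122 genes in both authors' deposited tables; each point is a gene and the dashed line marks equal change. Of these, 117 lie in the quadrants of equal direction (circles) and 5 in the opposite ones (triangles).

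Expression and splicing changes fell in the same genes in prmt5-5 more than in picln-1 by count, a difference that was not tested. In prmt5-5, 393 listed genes also held a called bin, where 104.5 were expected against all annotated genes (odds ratio 5.37, p = 1.14e-124, Fisher's exact test) and 237.8 against the genes tested (odds ratio 2.03, p = 4.62e-27). PTB1, FLK, SR34A and AT1G12730 are genes of that kind, and 359 of the 393 rose in expression. How far a rise in reads eases the call of a bin was not tested, and whether intron reads count toward expression is not given. In picln-1 only 12 genes held both, U1-70K among them, where 3.44 were expected against all annotated genes (odds ratio 3.67, exact p = 0.000205). Against the genes tested the picln-1 odds ratio was 1.54 (exact p = 0.144), so that call did not hold.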

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

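The grouping of fallen introns by splicing-factor genes and its test above a wild-type retained fraction of 0.1 were chosen after the results were seen, as were the comparisons of single genes and bins between the mutants.

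Of called intron bins 91.6% rose in picln-1 and 98.8% in prmt5-5, a difference of -7.16 points (p = 2.57e-17, Fisher's exact test), with 44 and 42 falls, so the shares differ through the number of rises (479 and 3320). The 44 introns that fell in picln-1 were rich in genes of the snRNP and SR and hnRNP-like lists, with 7 of 44 (U1-70K, GEMIN2, GRP8, PTB1, RS40, SCL33 and U2AF65B), against 0 of 479 introns that rose (p = 1.88e-08, Fisher's exact test). Only an intron retained in WT can fall. Among called introns with a WT fraction above 0.1 the contrast was still 7 of 40 against 0 of 106 (exact p = 7.69e-05). All of these had room to fall past the limit on the change, so that limit alone does not give the contrast there. WT levels above the cut were not matched, and the grouping was formed after these genes were seen. The contrast therefore cannot decide on unequal room to fall, which stays open. Splicing-factor genes might also give more power to call a fall, and in prmt5-5, which shares the WT values, they were again more common among introns that fell, with 2 of 42 against 14 of 3320 (exact p = 0.0164), though not past the threshold above a WT fraction of 0.1 (2 of 40 against 1.02% of introns that rose, exact p = 0.0980). That explanation and an untested effect of the mutation itself stay open, since the 2 genes, GEMIN2 and U2AF65B, are also among the 7 of picln-1 and share its WT values.

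Of the genes listed in both mutants, 5 moved in opposite directions. AT3G09160 fell in picln-1 (log2 change -1.47 in the authors' deposited table) and rose in prmt5-5 (0.65), a difference of 2.12. AT4G00520 went the same ways, with a difference of 1.3. The egg cell gene EC1.4 rose in picln-1 (1.0) and fell in prmt5-5 (-1.97) in the authors' deposited table, a difference of -2.97. AT5G24155 and AT3G10185 also rose in picln-1 and fell in prmt5-5, with differences of -2.10 and -1.3.

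Of the bins listed in both mutants, 3 moved in opposite directions, each with lower usage in picln-1 and higher usage in prmt5-5. The bin of AT2G35390 is an annotated retained intron, and its usage differed by 2.23 on the log2 scale. An intron of the glutamate synthase gene GLT1 differed by 1.47, and the intron of the SR protein gene SCL33 named above by 1.2.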

How the results depend on the processing

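The backgrounds of the genes tested, the direction read from the retained fraction and the removal of features with identical values were chosen after seeing the data. Of 51 alternatives over 19 results, 40 left the result on its side of the threshold or within 1.5 times its count, and none reversed a direction. An adjusted p below 0.01 left 279 bins in picln-1 (541 as deposited), 112 shared bins that rose (243) and 7 that fell (14), and 1 gene list past 0.05 among genes with called bins in picln-1 (3). A log2 change of at least 1 left 76 genes in picln-1 (279) and 427 in prmt5-5 (1531), and brought the odds ratio of the event mix to 0.479 (exact p = 0.262), with fewer bins other than introns (18 to 4 in picln-1). For genes in picln-1 that hold both an expression and a splicing change, the odds ratio was 1.80 (exact p = 0.0749) with a background of 19047 genes and 1.54 (exact p = 0.144) with the genes tested, against 3.67 with all annotated genes. The number of lists past 0.05 for expression in picln-1 was 1 and 0 with these backgrounds, against 2, since a smaller background raises the number expected by chance. The share of intron bins that rose stayed between 90.8 and 93.3% in picln-1 and between 98.7 and 99.5% in prmt5-5 under every alternative run. None of these alternatives leaves out introns retained too little in WT to fall by 0.05. Above a WT fraction of 0.1, outside the snRNP and SR and hnRNP-like lists, 106 rose and 33 fell in picln-1. In prmt5-5 these counts were 390 and 38. No paired analysis was possible because the tables hold no values per library, although the library labels of the 3 genotypes share letters. The refits without each replicate, without a count filter and with another normalization were not run for the same reason, and the depth behind each fraction is unknown.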

Other observations

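Every test in this part except those of the 5' splice site score over all introns gained in a mutant was chosen after the results were seen.

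Light-harvesting genes rose together in prmt5-5. Of 9 genes with an LHCB symbol in the reference annotation, which encode chlorophyll-binding proteins of photosystem II antennae, 7 were listed, all higher (adjusted p = 0.000299 over 186 gene families, Fisher's exact test). The families adjusted over were only those with a listed member in the mutant, which makes the adjusted p of families too lenient. In the authors' deposited table the log2 changes were 2.40 for LHCB2.2, 1.91 for LHCB2.1 and LHCB2.3, 1.36 for LHCB3, 1.06 for LHCB4.2, 0.84 for LHCB6 and 0.81 for LHCB5, and the LHCB2 genes are close copies between which reads could be split. Of 6 LHCA genes of photosystem I, 4 were listed and all were higher, LHCA4 by 1.37 on the log2 scale in the authors' deposited table, but that family did not pass (adjusted p = 0.0835). No family passed among the 44 with a listed member in picln-1, where the lowest adjusted p (Fisher's exact test) was 0.18, for the small RNA precursors TAS1B and TAS1C, both lower.

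In prmt5-5, listed genes that held an intron with gained retention mostly rose: 352 were higher and 33 lower (91.4% higher), against 42.2% of the listed genes without such an intron, 484 higher and 662 lower (odds ratio 14.6, p = 7.91e-72, Fisher's exact test). In picln-1 the genes with such an intron were 4 higher and 6 lower (40% higher, against 41.3% of the others, exact p = 1), too few to show whether the link is absent. Whether intron reads count toward a gene's expression is not given, and how far more reads ease the call of an intron was not tested. A link made by the counting itself can therefore not be told apart in prmt5-5. Listed genes also lay next to each other more often than random genes, with 15 neighbouring pairs in picln-1 against a mean of 4.18, and 197 in prmt5-5 against 138.3 (permutation p = 0.0001 for each, the smallest that 10000 draws can give). Neighbours that could share reads, such as the overlapping MRD1 and HEI10 in picln-1, could add to these counts. Values identical to those of another listed gene occurred too, as for the neighbouring AT14A copies AT3G28290 and AT3G28300 (log2 change 1.63 each in picln-1 in the authors' deposited table).

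The introns that gained retention in prmt5-5 had weaker 5' splice sites than uncalled introns of the same genes, by -1.97 bits ± 0.0412 (SE, 2458 genes, sign-flip permutation p = 1e-05, the smallest possible). They less often had G at the last exon base (57.6% against 78.0%) and at intron base 5 (37.8% against 49.9%), while 3' splice site scores differed by 0.0894 bits ± 0.0567 (permutation p = 0.115). Among introns retained in WT at no more than the median of 2.44% the 5' difference was -1.99 bits (permutation p = 1e-05), and in picln-1, at no more than 4.53%, -0.308 bits ± 0.147 (permutation p = 0.0367). In picln-1 the difference over all introns with gained retention was -0.447 bits ± 0.112 (SE, 392 genes, permutation p = 9e-05), and introns of different classes differed. Introns gained in both mutants scored -1.12 bits ± 0.169 against introns called in neither (197 genes, permutation p = 1e-05), and introns gained in picln-1 alone -0.0133 bits ± 0.131 (214 genes, permutation p = 0.919). Introns gained in picln-1 were richer in GC than uncalled introns of the same genes, by 1.52 points ± 0.203 (permutation p = 1e-05). Over genes with gained introns in a single mutant, the difference was 0.232 bits ± 0.173 in picln-1 (permutation p = 0.183) and -2.03 bits ± 0.0433 in prmt5-5, and the mutants differed by -2.26 bits (permutation p = 1e-05). Leaving out what was called in prmt5-5 can itself remove weak 5' splice sites from the picln-1 side of these comparisons.

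Wholly unspliced RNA or genomic DNA would carry all introns of a gene alike. The differences of -1.97 bits in prmt5-5 and -1.12 bits for introns gained in both, far beyond a bound of 0.2 bits, argue against these as the whole cause there. Partly spliced RNA need not carry the introns of a gene alike, so the score cannot decide on it. Over all introns gained in picln-1 the difference of -0.447 bits also lay beyond the bound of 0.2 bits. The -0.308 bits of the less retained introns did not by its standard error. Called and uncalled introns of the same genes also differed in GC (1.52 points ± 0.203) over all introns gained in picln-1. G at the last exon base was less common too (70.8% against 77.8%, permutation p = 0.00539). Over that whole set these values argue against wholly unspliced RNA or genomic DNA as the whole cause. They were not split by class, so this source is not excluded in picln-1 outside the introns gained in both. Shorter introns are argued against in prmt5-5, where called introns were longer by 0.0920 ± 0.0186 in log2 length, and in picln-1 they cannot be told apart from no difference in length (-0.0898 ± 0.0555, permutation p = 0.106), because the value lies within its 95% limits of 0. For introns gained in prmt5-5 or in both mutants, the values are consistent with retention that depends on the strength of the 5' splice site, as a hypothesis. For introns gained in picln-1 alone, the difference was -0.0133 bits. That class leaves out every intron called in prmt5-5, a set with weak 5' splice sites, so its value cannot decide on weak 5' splice sites. A value within 0.2 bits is also what unspliced RNA or genomic DNA could give, so that source stays open there.

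Genes that moved the same way in both mutants might do so through the shared WT libraries, which add the same shift to both comparisons. Of the 117 such genes, 30 (25.6%) differed between the mutants by more than their approximate 95% limits. Those limits treat the comparisons as independent although WT is shared, so equal shifts alone allow at most about 5%. The 25.6% argues against the shared libraries as the whole cause. That value bears in the same way on any difference of the WT seedlings from both mutants, which would also add equal shifts. As part of the changes, and for the genes that did not differ between the mutants, a shift of WT stays open, as do effects that pICln and PRMT5 share in snRNP assembly, which were not tested.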
